A study of Mus musculus with 9 samples.

How the data were processed

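RNA sequencing of total RNA from the mouse dendritic cell line DC2.4 gave 9 libraries, 3 in each of the groups OMVSSDC, PBSDC and ZJDC, which were taken from the sample titles. Per the submitters' processing notes, reads were filtered with fastp 0.22.0, aligned with HISAT2 2.1.0 and counted with HTSeq 0.9.1. The deposited table gives read counts per gene, which the authors made without further normalization, as whole numbers. It also gives FPKM values, which the authors derived from the counts; on checking, each FPKM equalled the count divided by the table's gene length and the library's total. FPKM were not analysed further. The genome build and annotation are not given in the sources used here.

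The table holds 21959 genes, of which 4916 had 0 counts in every library and 13 are mitochondrially encoded. All 9 count columns were used. Genes whose symbol occurs in several lines of the table were kept apart by their identifier. Library totals ranged from 12784931 to 18388959 counts, and 3 counts, the limit that a count of 0 allows, correspond to 0.163 to 0.235 CPM.

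Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 11568. Libraries were scaled with TMM, and a quasi-likelihood model with robust estimation was fitted to all 9 libraries with the group as the only factor, leaving 6 residual degrees of freedom. The 3 comparisons were contrasts of that model, tested two-sided with the quasi-likelihood F-test and adjusted by Benjamini-Hochberg over all tested genes. A gene passed at an adjusted p under 0.05. Fold changes are on the log2 scale, the standard error is the fold change divided by the square root of F, and mean CPM are TMM-scaled.

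In total 25 gene lists were fixed, and 24 with at least 3 measured genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with the correlation estimated from the data. Within each list, genes were also adjusted over the list alone. The lists cover dendritic cell maturation, interferon and NF-kB responses, MHC class I and II, sensing, immune inhibitory molecules, cell cycle, p53, stress, NRF2, heat shock, sterol, glycolysis, oxidative phosphorylation, ribosomal proteins, lysosome, cytoskeleton and migration, immediate early genes, myeloid identity, and markers of epithelial, lymphoid, fibroblast or endothelial, and granulocyte or erythroid cells. The groups, the tests, the gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined.

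Genes were named by 3 parts of that rule. The first was a panel of 14 genes, named whatever its result. The second was the largest changes per direction (6 for OMVSSDC against PBSDC, 4 otherwise) among genes past the threshold, with a mean of at least 5 CPM, groups that did not overlap and an established symbol. The third was the 2 members with the smallest adjusted p from the lists with the smallest camera p (6 or 4 lists). Further list members named as examples were chosen after their values were seen. That choice was widened once results under other settings were known; several genes were dropped from it, some after their calls proved fragile, and put back before the texts were written, so that they are counted among the alternatives. Some list members are not reported singly here, and the counts of named genes under other settings leave them out.

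Gene Ontology biological process terms come from the deposited table. The test was added after the table was seen to hold them: Fisher's exact test, one-sided, per direction, over 2132 terms of 10 to 500 genes in a background of 11150 tested genes with a term, adjusted by Benjamini-Hochberg. Genes over 2-fold were used for both comparisons with PBSDC. For OMVSSDC against ZJDC all called genes were used, a rule chosen after 15 genes were found over 2-fold. Shared calls were set beside the number expected of independent lists and beside 40 simulations of groups that do not differ, in which the same PBSDC libraries serve both comparisons. Shares of counts were compared with two-sided exact permutation tests.

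The pipeline was tested on simulated data. Of genes simulated at 2-fold it recovered 46 of 50 for OMVSSDC against PBSDC, 47 of 50 for ZJDC against PBSDC and 48 of 50 for OMVSSDC against ZJDC, with 14 of 197, 10 of 193 and 8 of 191 calls false. The simulated spread came from the PBSDC and ZJDC libraries alone, here and in the simulations of shared calls. These values therefore do not cover the spread of the real OMVSSDC group.

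Settings of that first set were other scalings (RLE, library size alone), no filter or a stricter one, DESeq2 1.42.0, limma-voom, the replicate number as a block, glmTreat with a fold of 1.2, only the 2 groups compared, and each library left out in turn. Alternatives for tables with normalized values alone were not run, since counts were present. Added after the data were seen were fits within the 7 libraries that share traces of heart and brain transcripts, without all OMVSSDC libraries, for ZJDC against PBSDC without OMVSSDC replicate 3, without mitochondrially encoded genes, and with a trend on gene length and transcript GC content removed per library. GC content came from the longest GENCODE transcript of each gene and was available for 99.7% of tested genes. The heart, brain and liver marker lists were written after such traces were noticed. Genes of these lists with a mean of 1 CPM or more (9 of 18 heart, 5 of 16 brain and 2 of 13 liver genes) were left out of the sums, also after unfiltered sums had been seen; the unfiltered heart and brain sums were 74.6 and 74.9 CPM in OMVSSDC replicates 1 and 2 and 91.7 to 112 CPM in the others. In fits with OMVSSDC replicate 3 alone, that library is assumed to vary like the other groups.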

Results

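Messenger RNA levels were measured by sequencing total RNA from DC2.4, a mouse dendritic cell line, in 9 libraries. The libraries fall into 3 groups of 3, labelled OMVSSDC, PBSDC and ZJDC. The study's description names engineered extracellular vesicles as the treatment and immune-related genes as the interest. The labels do not say what OMVSS or ZJ stand for, which of these groups received the named vesicles, at what dose or for how long. PBS conventionally abbreviates phosphate-buffered saline, and PBSDC served as the reference group. On that reading OMVSSDC and ZJDC are called treated groups here, which the labels do not state. The labels also do not say whether libraries of a group came from separate cultures, so the spread within a group may be technical only and the p-values may be too small.

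Total counts were 13037337, 16784411 and 14711484 in OMVSSDC replicates 1, 2 and 3. They were 17770675, 15247660 and 14291947 in PBSDC and 17942974, 12784931 and 18388959 in ZJDC. Between 13858 and 14362 genes had at least 1 count in a library. A count of 0 allows a level of up to 3 counts, which is 0.163 to 0.235 CPM (counts scaled to a common library total) depending on the library. Such limits cover counting error only. After the filter on low counts, 11568 genes were tested.

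On the first principal component, with 72.8% of the variance, PBSDC lay apart from both treated groups. On the second, with 14.6%, OMVSSDC replicates 1 and 2 lay apart from OMVSSDC replicate 3, which lay among the ZJDC libraries there and, on the first, between ZJDC and replicates 1 and 2. The chi-square per degree of freedom between replicates 1 and 2 was 1.89, against 62.4 and 65.1 between each of them and replicate 3. Replicate 3 differed from the ZJDC libraries by 7.75 to 10.7, and libraries within ZJDC differed by 2.57 to 9.01. Traces of 20 heart and brain marker genes followed the same division. They summed to 1.30 and 1.73 CPM in OMVSSDC replicates 1 and 2 and to 5.60 to 10.8 CPM in the other 7 libraries. Replicates 1 and 2 were therefore treated as a possible batch, which holds libraries of OMVSSDC only. In fits without OMVSSDC replicate 3, OMVSSDC is that possible batch alone, so batch and treatment cannot be told apart there. Values within the other 7 libraries, with OMVSSDC replicate 3 alone against the other groups, are given where they differ. Such fits measure no spread within OMVSSDC. Their p-values assume the spread of the other groups and describe 1 library, not the group.

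**Figure D1:**
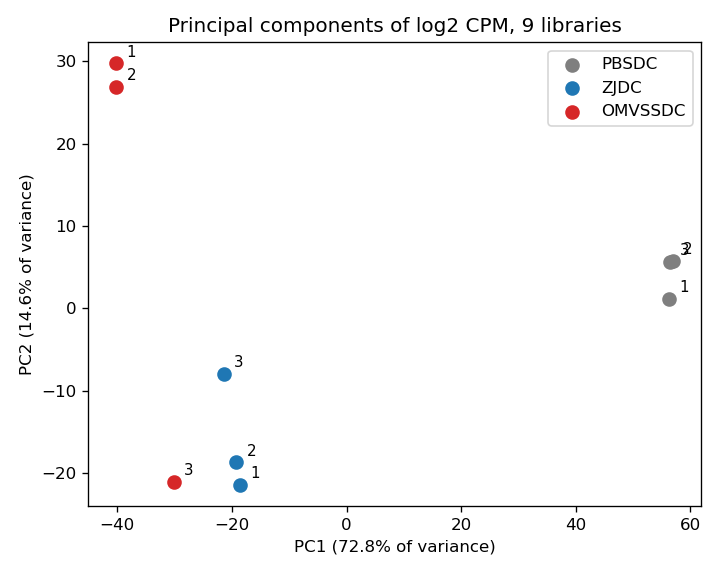
Scores of the 9 libraries on the first and second principal components of log2 CPM, with 72.8% and 14.6% of the variance; each point is a library, coloured by group and numbered by replicate. OMVSSDC replicate 3 lies among the ZJDC libraries on the second axis, at -21.1, while replicates 1 and 2 lie at 29.7 and 26.9.

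The comparison of OMVSSDC with PBSDC asks which genes differed between these treated cells and the reference. Genes of the NF-kB and Toll-like receptor response were higher in OMVSSDC. Il6, a proinflammatory cytokine, rose from 4.98 ± 1.08 to 59.6 ± 3.56 CPM (SD, n = 3 in each group; adjusted p = 2.29e-08). Cd274, which encodes the inhibitory ligand PD-L1, rose from 19.1 ± 0.356 CPM to 152 CPM (SE of the log2 fold change 0.0920; adjusted p = 1.0e-08). Cd40 and Cd86, which encode costimulatory molecules, rose by log2 fold changes of 1.64 (SE 0.126) and 1.17 (SE 0.0626). Cell cycle genes and sterol synthesis genes were lower. In all, 7358 of 11568 genes passed (63.6%), 3866 higher and 3492 lower (3430 and 4153 with the length and GC trend removed), and 1494 of the higher and 795 of the lower differed by over 2-fold. Groups did not overlap for 65.7% of genes, where chance gives 10%.

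Of the core panel, Tnf rose by 0.66 (SE 0.0637), H2-K1 by 1.68 (SE 0.101) and B2m by 0.75 (SE 0.171) on the log2 scale. H2-K1 encodes a classical MHC class I heavy chain and B2m its light chain. Il12b, a subunit of the T cell polarising cytokine IL-12, had 18, 25 and 25 counts in OMVSSDC and 2, 0 and 2 in PBSDC (adjusted p = 8.48e-05). Cxcl10, a chemokine induced by interferons, rose by 0.60 (adjusted p = 0.0274), but did not pass without PBSDC replicate 1 (0.0930) or PBSDC replicate 2 (0.0875). Cd80, which encodes another costimulatory molecule, had a log2 fold change of -0.05 (SE 0.156, adjusted p = 0.793). Cd83, Ccr7, H2-Ab1 and Ifnb1 did not pass the filter on low counts. Cd83 had 17, 21 and 8 counts in OMVSSDC and 4, 0 and 1 in PBSDC, and was higher when no filter was applied (3.07, SE 0.767, adjusted p = 0.00421). The others did not pass without the filter either (adjusted p = 0.370 to 0.594). Ccr7 had at most 2 in any of these 6 libraries. H2-Ab1 had 7, 6 and 4 against 0, 6 and 5, and Ifnb1 1, 0 and 0 against 1, 2 and 0.

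Among 14 measured genes of dendritic cell maturation and costimulation, 10 rose and 3 fell (10 and 3 adjusted over the list alone). The list passed with an adjusted p of 0.0296, which was 0.110 as adjusted p with an estimated correlation. It did not pass without OMVSSDC replicate 3 (0.0553) or within the 7 libraries (0.0540). Icam1, an adhesion molecule, fell by 1.53 on the log2 scale. Of 40 genes of the NF-kB and Toll-like receptor response, 32 rose and 2 fell (33 and 2 adjusted over the list alone; list adjusted p = 1.40e-08). Lcn2, an iron-sequestering protein of innate defence, rose from 547 ± 24.4 to 3421 ± 55.4 CPM, and Csf1, a macrophage growth factor, by 3.30. Il23a, a subunit of IL-23, rose by 3.56 and Ptgs2, the inducible cyclooxygenase, by 2.79. Il1b, a proinflammatory cytokine, fell by 2.59 at a low level, 1.87 CPM in PBSDC and 0.294 CPM in OMVSSDC.

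Interferon-related lists rose together. Of 39 antiviral interferon-stimulated genes, 33 rose and 1 fell (34 and 1 adjusted over the list alone), with a list adjusted p of 3.01e-09 and 0.0577 as adjusted p with an estimated correlation. Rsad2, the antiviral protein viperin, rose by 3.18 (SE 0.0804), Oasl1 by 2.77 and the ubiquitin-like Isg15 by 2.52. Of 18 interferon-induced GTPases and interferon gamma response genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone; list adjusted p = 0.000115). Gbp8, a guanylate-binding protein, rose from 7.69 ± 0.630 to 144 ± 13.3 CPM. Of 23 genes of MHC class I processing and presentation, 18 rose and 3 fell (18 and 3 adjusted over the list alone; list adjusted p = 0.000637, and adjusted p = 0.261 with an estimated correlation). H2-D1 rose by 2.16, H2-T23 by 2.93 and Nlrc5, a transactivator of these genes, by 1.97. Within the 7 libraries H2-T23 was 2.28 higher. The 3 that fell, Calr (-0.96), Pdia3 (-0.93) and Canx (-0.48), encode chaperones of the endoplasmic reticulum. Guanylate-binding, class I, Oas and Ly6 genes have close relatives, and how shared reads were assigned is not stated.

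Among 18 immune inhibitory molecules, 11 rose and 3 fell (11 and 3 adjusted over the list alone; list adjusted p = 0.0296, and adjusted p = 0.110 with an estimated correlation). Without PBSDC replicate 1 the list did not pass (0.0667). Beside Cd274, Entpd1, which degrades extracellular ATP, rose by 1.95 and Cd276 by 1.95. Havcr2, which encodes TIM-3, fell by 1.53. The anti-inflammatory cytokine Il10 fell by 0.76 (adjusted p = 0.0326), and each of 5 left-out libraries ended that call: OMVSSDC replicates 1, 2 and 3 (0.0530, 0.112 and 0.0556) and PBSDC replicates 2 and 3 (0.0974 and 0.102). Of 28 immediate early genes, 19 rose and 3 fell (20 and 3 adjusted over the list alone; list adjusted p = 0.000389, and adjusted p = 0.0560 with an estimated correlation). The transcription factor genes Egr1 and Fos rose by 3.10 and 2.02, and Dusp5, a phosphatase acting on ERK, by 2.25.

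Of 37 cell cycle genes, 0 rose and 36 fell (0 and 36 adjusted over the list alone), the exception being Cdt1. The list adjusted p was 1.10e-14. Kif20a, a mitotic kinesin, fell from 97.2 ± 2.36 to 24.5 ± 1.55 CPM, and Rrm1, a subunit of ribonucleotide reductase, fell by 1.69 (SE 0.0673). Of 28 genes of sterol biosynthesis and uptake, 0 rose and 24 fell (1 and 24 adjusted over the list alone; list adjusted p = 5.36e-08). Idi1 and Fdps, enzymes of isoprenoid synthesis, fell by 2.08 and 2.11, and Acat2 by 1.79. Of 14 heat shock genes, 2 rose and 11 fell (2 and 12 adjusted over the list alone; list adjusted p = 0.00146, and adjusted p = 0.261 with an estimated correlation). The chaperone genes Hsp90aa1, Hsp90ab1 and Hspa8 fell by 1.13, 1.09 and 1.08, and Hspa4l rose by 1.16.

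Of 38 genes of lysosome, endocytosis and autophagy, 25 rose and 7 fell (27 and 7 adjusted over the list alone; list adjusted p = 0.000495). Sqstm1, an autophagy receptor, rose by 2.18 and Ctsb, a lysosomal protease, by 1.14, while the scavenger receptor gene Cd36 fell by 1.12. Mrc1, the mannose receptor, fell by 2.86 from 1.29 CPM in PBSDC; the value was -3.68 without OMVSSDC replicate 3 and -1.92 within the 7 libraries. Of 21 NRF2 genes, 13 rose and 5 fell (13 and 5 adjusted over the list alone; list adjusted p = 0.0446, and adjusted p = 0.290 with an estimated correlation). Slc7a11, a cystine transporter subunit, rose by 2.19 and the ferritin heavy chain gene Fth1 by 1.56. The NRF2 list did not pass without OMVSSDC replicate 1 (0.0530), without PBSDC replicate 3 (0.0565), with a replicate block (0.0514) or within the 7 libraries (0.108). Of 21 p53 targets, 12 rose and 2 fell (12 and 3 adjusted over the list alone; list adjusted p = 0.0437, and adjusted p = 0.115 with an estimated correlation). The p53 list did not pass without PBSDC replicates 1, 2 or 3 (0.0519, 0.0509 and 0.0501) or with a replicate block (0.0501). Plk2 rose by 2.09, Cdkn1a, an inhibitor of cyclin-dependent kinases, by 0.52, and the apoptosis gene Bbc3 by 2.70, or 1.72 within the 7 libraries.

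Of 53 cytoplasmic ribosomal protein genes, 32 rose and 2 fell (32 and 2 adjusted over the list alone; list adjusted p = 0.00691, and adjusted p = 0.732 with an estimated correlation). These genes took 3.17% and 3.10% of counts in OMVSSDC replicates 1 and 2 and 2.16% in replicate 3, against 1.95% to 1.98% in PBSDC. Within the 7 libraries the list had an adjusted p of 0.726, Rplp1 moved from 1.48 to 0.17 and Rps19 from 1.46 to -0.04. Rps10 was lower by this test (-0.68, adjusted p = 0.0447) and did not pass without OMVSSDC replicate 2 (0.139), PBSDC replicate 2 (0.128) or PBSDC replicate 3 (0.135), nor within the 7 libraries (0.102).

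The largest increases at a mean of 5 CPM or more were in Heatr9, Ccl5, Ccbe1, Slamf7, Syt7 and Sh2d6, and the largest decreases in Trem1, Dmpk, mt-Cytb, mt-Nd1, Cx3cr1 and mt-Nd2. Heatr9 had 377, 520 and 417 counts in OMVSSDC and 2, 0 and 6 in PBSDC, with a log2 fold change of 7.25 (SE 0.340) that was 8.62 without PBSDC replicate 3. Ccl5, a chemokine that attracts T cells, lies near it on chromosome 11, at 83416604 to 83421344 against 83402562 to 83413001 for Heatr9; the genome build is not given in the sources used here. Ccl5 rose from 4.75 ± 0.389 to 281 ± 117 CPM, a log2 fold change of 5.88 that was 4.93 within the 7 libraries. Slamf7, an immune cell receptor, rose from 3.55 ± 0.916 to 175 ± 27.2 CPM, and Sh2d6 from 11.3 ± 1.42 to 339 ± 10.7 CPM. Ccbe1 and Syt7 rose by 5.64 and 5.63. Trem1, a receptor that amplifies myeloid inflammation, had 222, 197 and 171 counts in PBSDC and 4, 0 and 2 in OMVSSDC. Its log2 fold change was -6.57, and -7.56 and -5.91 without OMVSSDC replicates 1 and 2. Dmpk had 157, 170 and 139 counts against 2, 1 and 2. Cx3cr1, the fractalkine receptor, fell from 17.2 ± 1.71 to 1.18 ± 0.286 CPM.

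Among 12 measured mitochondrially encoded genes, which encode subunits of the respiratory chain and ATP synthase, 11 fell. Their counted levels differed widely. In PBSDC mt-Co1 stood at 26382 CPM and mt-Co2, mt-Atp6 and mt-Co3 at 67.9, 32.3 and 28.5 CPM. How reads that match several places in the genome were assigned is not stated. The counted levels and fold changes of these genes may therefore differ from those of their transcripts. The genes mt-Nd3 and mt-Nd4l fell from 1.73 and 1.63 CPM to 0.282 and 0.259 CPM, near the lowest level that could be measured. Log2 fold changes were -4.12 for mt-Cytb, -3.93 for mt-Nd1 and -3.69 for mt-Nd2. They were -3.42, -3.11 and -2.73 within the 7 libraries, and without OMVSSDC replicate 3 mt-Nd1 and mt-Nd2 stood at -4.62 and -4.61. The exception, mt-Co1, had -0.35 (adjusted p = 0.305), which was -0.91 without OMVSSDC replicate 3 (0.000214) and 0.35 within the 7 libraries. The 42 nuclear genes of oxidative phosphorylation did not pass as a list (7 higher, 10 lower, or 6 and 8 adjusted over the list alone; list adjusted p = 0.550), but within the 7 libraries the list was lower (adjusted p = 1.91e-05, and adjusted p = 0.333 with an estimated correlation).

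Gene Ontology biological process terms, taken from the deposited table, were tested among genes called over 2-fold, and 26 of 2132 terms passed among higher genes and 50 among lower genes (14 and 37 without OMVSSDC replicate 3, and 12 and 137 among all called genes). G protein-coupled receptor signaling held 56 higher genes of 196 (adjusted p = 3.60e-06) and immune system process 83 of 362 (2.99e-05), with 35 lower genes also in the latter. Response to virus held 26 of 76 (0.000518), and presentation of endogenous peptide through MHC class Ib 10 of 12 (3.74e-05). Inflammatory response passed both ways, with 46 higher (0.0128) and 28 lower genes (0.0303) of 207. Among lower genes, cell division held 66 of 331 (7.50e-12), DNA replication 31 of 110 (6.53e-09) and RNA splicing 44 of 258 (7.87e-06). Of 24 lists tested, 14 passed, and 5 held with an estimated correlation: the interferon-induced GTPases, NF-kB, cell cycle, sterol and lysosome lists. These 5 did not pass within the 7 libraries with an estimated correlation (adjusted p = 0.157 each).

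**Figure D2:**
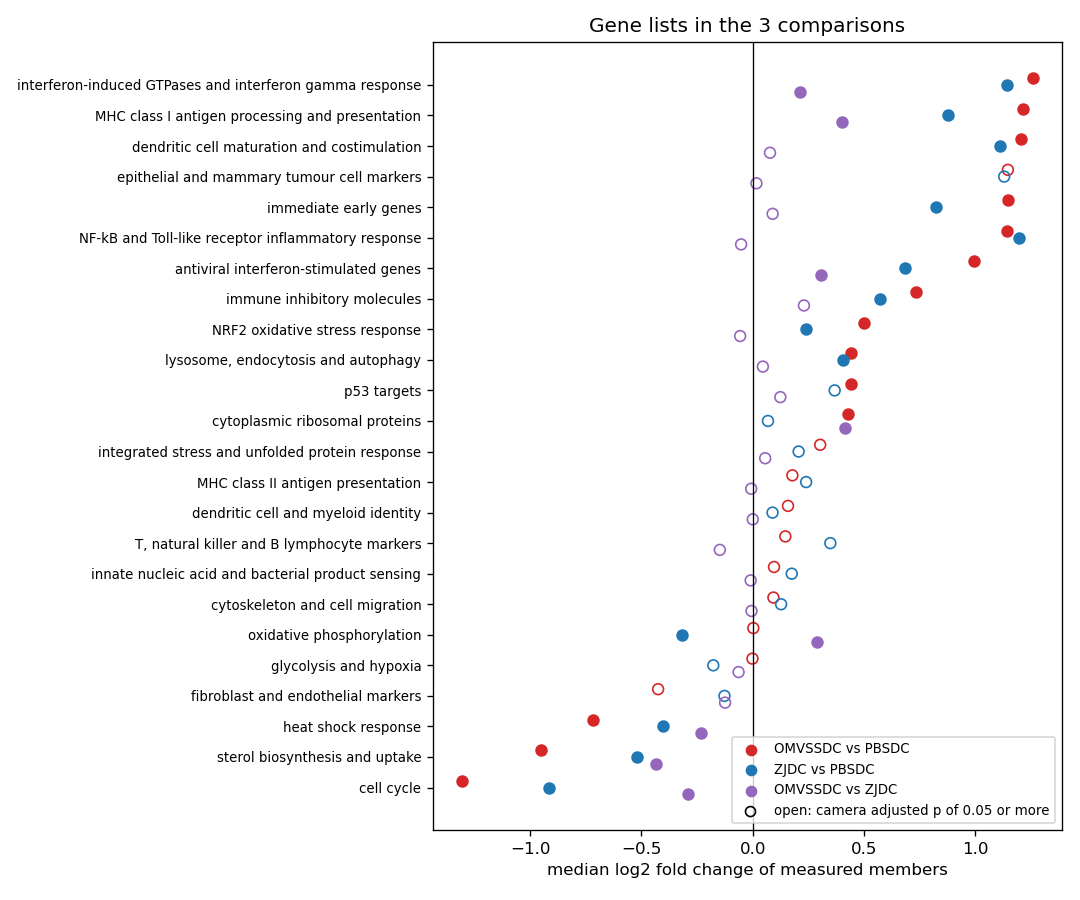
Median log2 fold change of the measured members of each gene list in the 3 comparisons; filled symbols mark lists whose camera adjusted p was under 0.05 and open symbols the others. Cell cycle, sterol and heat shock lists lie below 0 in all 3 comparisons, with 36, 24 and 11 lower genes in OMVSSDC against PBSDC.

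ZJDC was compared with PBSDC to ask which genes differed between these other treated cells and the reference. Genes of the NF-kB and Toll-like receptor response were higher in ZJDC and cell cycle genes lower. Il6 rose from 4.98 ± 1.08 to 63.4 ± 1.41 CPM (SD, n = 3 in each group; adjusted p = 2.45e-08), and Cd274 from 19.1 ± 0.356 to 131 ± 2.91 CPM. Cd86 and Cd40 rose by log2 fold changes of 1.13 (SE 0.0625) and 1.10 (SE 0.125). Acod1, which makes the antimicrobial metabolite itaconate, rose from 239 ± 5.67 to 1854 ± 21.0 CPM. Of 11568 genes, 6323 passed (54.7%), 3193 higher and 3130 lower (2891 and 3940 with that trend removed), and 1062 and 450 of these differed by over 2-fold. Groups did not overlap for 72.2% of genes, where chance gives 10%.

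H2-K1 rose by 1.44, B2m by 0.92 (SE 0.171), Tnf by 0.86 (SE 0.0638) and Cxcl10 by 0.94 (SE 0.203). Il12b had 17, 8 and 19 counts in ZJDC (adjusted p = 0.000746 against PBSDC). Cd80 had a log2 fold change of 0.35 (adjusted p = 0.0752), and passed without OMVSSDC replicate 3 (0.0215), without ZJDC replicate 3 (0.0496), with library size alone (0.0321) and with only the 2 groups compared (0.0219). Counts in ZJDC were 6, 1 and 11 for Cd83, 4, 1 and 1 for Ccr7, 4, 4 and 5 for H2-Ab1 and 0, 0 and 0 for Ifnb1, none of which passed the filter on low counts or, without that filter, the test by edgeR (adjusted p = 0.174 to 0.975). Of 14 dendritic cell maturation genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone; list adjusted p = 0.00731, and adjusted p = 0.0628 with an estimated correlation), and Icam1 fell by 1.30. Of 40 NF-kB and Toll-like receptor response genes, 32 rose and 1 fell (32 and 1 adjusted over the list alone; list adjusted p = 1.0e-10). Csf1 rose by 3.37, Ptgs2 by 3.29, Il23a by 4.06 and the acute phase gene Saa3 by 3.70. Il1b fell by 2.48 from a low level, and stood at -3.43 without ZJDC replicate 3.

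Of 39 antiviral interferon-stimulated genes, 29 rose and 1 fell (29 and 1 adjusted over the list alone; list adjusted p = 1.63e-08, and adjusted p = 0.0628 with an estimated correlation). Rsad2 rose by 2.53, Oasl1 by 2.57 and Isg15 by 1.62. Of 18 interferon-induced GTPases and interferon gamma response genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone; list adjusted p = 0.000323, and adjusted p = 0.0566 with an estimated correlation). Gbp2 rose by 2.20 and Gbp5 by 3.21, the latter 3.99 without PBSDC replicate 2. Of 23 MHC class I genes, 14 rose and 3 fell (15 and 3 adjusted over the list alone; list adjusted p = 0.00478, and adjusted p = 0.349 with an estimated correlation). H2-D1 rose (adjusted p = 1.38e-05), and the 3 that fell were again the chaperone genes Calr (-0.83), Pdia3 (-0.81) and Canx (-0.44). Of 18 immune inhibitory molecules, 10 rose and 3 fell (11 and 3 adjusted over the list alone; list adjusted p = 0.0346, and adjusted p = 0.117 with an estimated correlation), and without PBSDC replicate 1 the list did not pass (0.0539). Entpd1 rose by 1.80, while Havcr2 and Il10 fell by 1.68 and 1.61. Of 28 immediate early genes, 19 rose and 3 fell (19 and 3 adjusted over the list alone; list adjusted p = 0.000117, and adjusted p = 0.0566 with an estimated correlation). Egr1 rose by 3.08. Nr4a3, an orphan nuclear receptor gene, rose by 2.62, but did not pass without PBSDC replicate 1 (1.99, adjusted p = 0.0518) and stood at 3.87 without PBSDC replicate 2.

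Of 37 cell cycle genes, 0 rose and 35 fell (0 and 35 adjusted over the list alone; list adjusted p = 1.51e-14). Kif20a fell by 1.69 (SE 0.0707) and Mcm7, a subunit of the replicative helicase, by 1.31 (SE 0.0715). Of 28 sterol genes, 2 rose and 20 fell (2 and 22 adjusted over the list alone; list adjusted p = 4.01e-05, and adjusted p = 0.0628 with an estimated correlation). Acat2 fell by 1.16, Fasn, the fatty acid synthase gene, by 1.09 and Fdps by 1.56. Fads1, a fatty acid desaturase gene, rose by 0.19 (adjusted p = 0.0145), and did not pass without PBSDC replicate 2 (0.0596) or ZJDC replicate 1 (0.0615). Of 14 heat shock genes, 2 rose and 11 fell (2 and 11 adjusted over the list alone; list adjusted p = 0.0146, and adjusted p = 0.378 with an estimated correlation), and without PBSDC replicate 3 the list did not pass (0.124). Hsp90aa1 and Hspa8 fell by 0.64 and 0.39. Of 42 nuclear genes of oxidative phosphorylation, 0 rose and 17 fell (0 and 15 adjusted over the list alone; list adjusted p = 0.00478, and adjusted p = 0.747 with an estimated correlation). Ndufs8, a complex I subunit gene, fell by 0.66. Cox7a2, of complex IV, fell by 0.86, and did not pass without ZJDC replicate 1 (0.0514).

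Of 38 lysosome, endocytosis and autophagy genes, 27 rose and 3 fell (27 and 3 adjusted over the list alone; list adjusted p = 4.01e-05). Sqstm1 rose by 1.88, and Mrc1 fell by 2.15. Of 21 NRF2 genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone; list adjusted p = 0.0146, and adjusted p = 0.217 with an estimated correlation), with Slc7a11 higher by 2.50 and Fth1 by 1.48. The p53 targets and ribosomal protein genes did not pass as lists (adjusted p = 0.0614 and 0.714). The largest increases were in Heatr9, Slamf7, Syt7 and Ccl5. Heatr9 had 239, 202 and 324 counts in ZJDC, a log2 fold change of 6.39 that was 7.77 without PBSDC replicate 3. Slamf7 reached 162 ± 5.15 CPM and Ccl5 116 ± 14.5 CPM, and Syt7 rose by 5.21. The largest decreases were in Dmpk, Trem1, Cx3cr1 and Fgd2. Dmpk had 1, 0 and 3 counts in ZJDC and Trem1 7, 2 and 13; without ZJDC replicate 3 their log2 fold changes moved from -6.86 to -7.99 and from -4.85 to -5.44. Cx3cr1 fell by 3.69 and Fgd2, a guanine nucleotide exchange factor, by 3.01.

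Of 12 measured mitochondrially encoded genes, 9 fell, with -2.61 for mt-Cytb, -2.39 for mt-Nd1 and -2.12 for mt-Nd2. The genes mt-Nd5 (-0.82, adjusted p = 0.131), mt-Nd6 (-0.70, 0.252) and mt-Co1 (0.47, 0.192) did not pass. Of these, mt-Co1 passed without OMVSSDC replicate 3 (adjusted p = 0.00333), a library of the other treated group that enters through the shared spread. Of 2132 terms, 27 passed among genes over 2-fold higher and 19 among lower (28 and 87 among all called genes). Immune response passed both ways, with 32 higher (adjusted p = 8.53e-05) and 15 lower genes (0.0257) of 125, as did inflammatory response, with 37 higher (0.00977) and 24 lower genes (0.00136) of 207. Cell division held 33 lower genes of 331 (0.00136). Without OMVSSDC replicate 3, 18 and 8 terms passed. Of 24 lists, 13 passed, and 3 held with an estimated correlation: the NF-kB, cell cycle and lysosome lists.

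**Figure D3:**
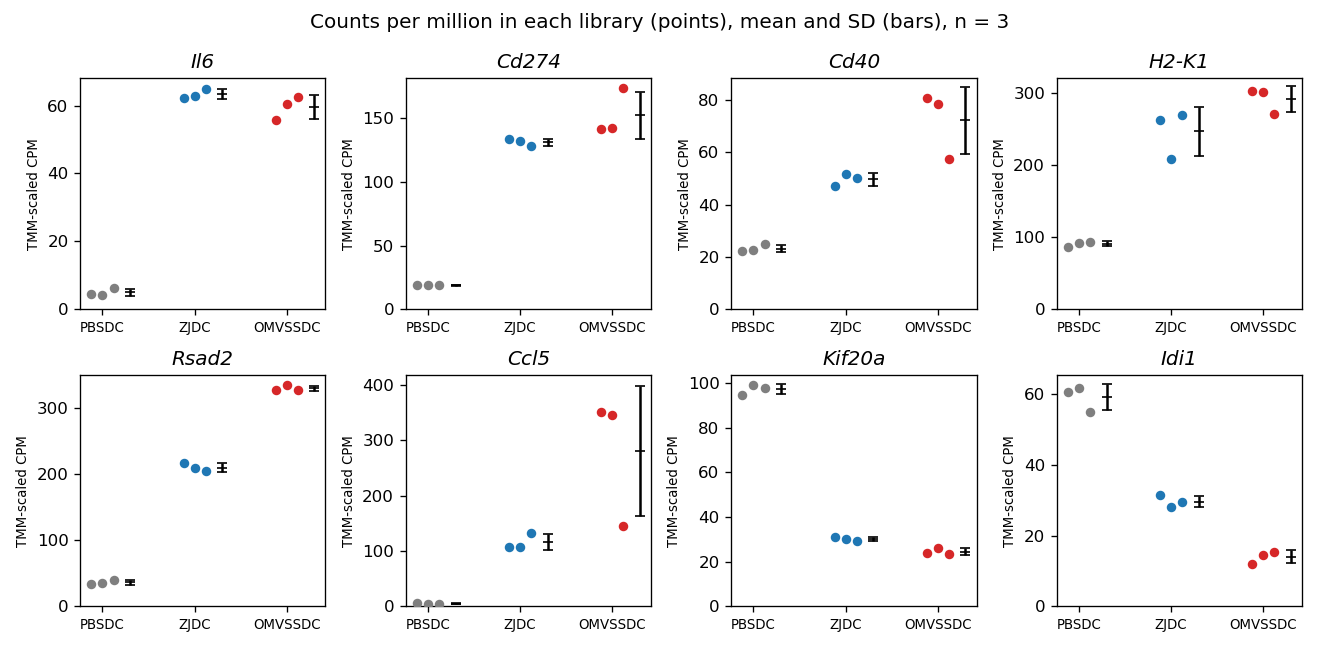
TMM-scaled CPM of 8 genes in each library (points) with the mean and SD of each group (bars, n = 3). Il6 and Cd274 lie at like levels in both treated groups, at 59.6 and 63.4 CPM and at 152 and 131 CPM; Ccl5 has an SD of 117 CPM in OMVSSDC.

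OMVSSDC was compared directly with ZJDC to ask where both treatments differed. The lists of interferon-stimulated and MHC class I genes were higher in OMVSSDC, and those of sterol, cell cycle and heat shock genes lower, with a minority of each passing as single genes; of these 5 lists the sterol and cell cycle lists held with an estimated correlation. Rsad2 stood at 329 ± 4.02 CPM in OMVSSDC and 209 ± 6.48 CPM in ZJDC (SD, n = 3 in each group; log2 fold change 0.65, SE 0.0729, adjusted p = 0.00892). Idi1 stood at 14.0 ± 1.81 and 29.6 ± 1.63 CPM (-1.08, SE 0.105, adjusted p = 0.00722). Of 11568 genes, 226 passed (1.95%), 99 higher and 127 lower (115 and 91 with library size alone), and 9 and 6 differed by over 2-fold. At an unadjusted p under 0.05 there were 3675, and groups did not overlap for 24.0% of genes, where chance gives 10%. The count rested on single libraries. It was 6, 2 and 6539 without OMVSSDC replicates 1, 2 and 3, and 0 without ZJDC replicates 1, 2 or 3 by edgeR (2122, 2341 and 3149 at an unadjusted p under 0.05). With all 6 libraries DESeq2 called 1580, limma-voom 323 and glmTreat 2, and edgeR called 0 with only the 2 groups compared (2558 at an unadjusted p under 0.05) and 0 with a replicate block (2955). The fit within the 7 libraries gave 355.

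None of the core panel passed with all libraries. Cd40 was nearest (0.54, adjusted p = 0.0538), followed by Tnf (-0.20, 0.0876), Cd80 (-0.40, 0.115), Cd274 (0.22, 0.115) and H2-K1 (0.24, 0.130). Il12b had 0.72 (0.162), Cxcl10 -0.35 (0.238), B2m -0.17 (0.493), Il6 -0.09 (0.558) and Cd86 0.05 (0.602). Without OMVSSDC replicate 3, 6 of them passed: Cd40 (0.68, adjusted p = 1.80e-09) and H2-K1 (0.28, 0.0274) higher, and Cd80 (-0.54, 0.00322), Tnf (-0.24, 2.74e-05), Cxcl10 (-0.47, 0.0214) and B2m (-0.46, 1.97e-09) lower. That fit holds only the possible batch for OMVSSDC, so batch and treatment cannot be told apart. Its OMVSSDC libraries lay close together (chi-square per degree of freedom 1.89), so its p-values may be too small. Within the 7 libraries, with OMVSSDC replicate 3 alone, B2m had the opposite direction (0.27) and Cd274 stood at 0.40. That fit measures no spread within OMVSSDC. Cd40 also passed with DESeq2 (0.00358), limma-voom (0.0496), no filter (0.0361) and the length and GC trend removed (0.0344), and Tnf with DESeq2 (0.0218) and that trend removed (0.0489).

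Of 39 antiviral interferon-stimulated genes, 11 rose and 0 fell (23 and 0 adjusted over the list alone; list adjusted p = 2.06e-06, and adjusted p = 0.222 with an estimated correlation). Mx1, an antiviral GTPase, was higher by 0.58, Isg15 by 0.90 and Ifit3 by 0.93. Of 18 interferon-induced GTPases, 0 passed as single genes (4 and 0 adjusted over the list alone), and the list passed (adjusted p = 0.00504, and adjusted p = 0.222 with an estimated correlation), but not without OMVSSDC replicate 3 (0.154). Of 23 MHC class I genes, 5 rose and 0 fell (14 and 0 adjusted over the list alone; list adjusted p = 4.19e-05, and adjusted p = 0.227 with an estimated correlation). H2-T23 was higher by 1.12, or 0.46 within the 7 libraries, H2-D1 by 0.67 and Nlrc5 by 0.44; within the 7 libraries Nlrc5 (0.0538) and Ifit3 (0.0550) did not pass. Of 28 sterol genes, 0 rose and 12 fell (0 and 19 adjusted over the list alone; list adjusted p = 6.25e-12). Fads2, a fatty acid desaturase gene, fell by 0.90 and Idi1 by 1.08. Of 37 cell cycle genes, 0 rose and 11 fell (1 and 27 adjusted over the list alone; list adjusted p = 1.78e-10). Bub1, a spindle checkpoint kinase, fell by 0.59, Rrm1 by 0.50 and Top2a by 0.49. Of 14 heat shock genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone; list adjusted p = 1.74e-05, and adjusted p = 0.223 with an estimated correlation), among them Hspa8 (-0.69) and Hsp90aa1 (-0.49).

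The largest increases were in Ly6a, Ccl5, Slfn1 and Ifi44l and the largest decreases in mt-Nd4, mt-Cytb, Idi1 and Ccne2. Ly6a, a surface antigen induced by interferons, stood at 19.4 ± 6.56 and 7.02 ± 0.166 CPM (1.47, adjusted p = 0.0281). Within the 7 libraries Ly6a was 0.76 higher, Ccl5 moved from 1.28 to 0.32 (0.0759), Ifi44l from 1.13 to 0.50 (0.0891) and mt-Nd4 from -1.52 to -0.76 (0.138). The value of mt-Cytb moved from -1.51 to -0.81, while mt-Nd4 stood at -2.15 without OMVSSDC replicate 3. Slfn1 had 1.21, and 1.08 within the 7 libraries. Ccne2, which encodes cyclin E2, had -0.94, and within the 7 libraries its adjusted p was 0.0538. Acod1 and Slc7a11 were lower in OMVSSDC by this test (-0.38 and -0.32).

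Of 42 nuclear genes of oxidative phosphorylation, 0 passed as single genes (0 adjusted over the list alone), and the list was higher in OMVSSDC (adjusted p = 4.19e-05, and adjusted p = 0.790 with an estimated correlation). Within the 7 libraries the direction turned, with the list lower (adjusted p = 0.000138, and adjusted p = 0.437 with an estimated correlation). Of 53 ribosomal protein genes, 0 passed as single genes (32 higher and 1 lower adjusted over the list alone), and the list was higher (adjusted p = 2.08e-06, and adjusted p = 0.608 with an estimated correlation); within the 7 libraries it pointed lower and did not pass (0.311). The remaining lists did not pass (adjusted p = 0.0953 to 0.986), but within the 7 libraries the NRF2 list was lower (adjusted p = 0.00505, and adjusted p = 0.254 with an estimated correlation). Of 24 lists, 8 passed, and 2 held with an estimated correlation: the cell cycle and sterol lists (adjusted p = 0.0785 each with it within the 7 libraries). Among all called genes, 8 terms passed for higher and 19 for lower, including response to virus with 8 higher genes of 76 (adjusted p = 0.000141) and cholesterol biosynthesis with 6 lower genes of 23 (0.000224). Among genes over 2-fold 0 terms passed Fisher's exact test (94 at an unadjusted p under 0.05), and 104 terms passed without OMVSSDC replicate 3.

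Both treated groups shared most of their differences from PBSDC. Of genes higher in OMVSSDC and in ZJDC, 2815 were shared, where independent lists would share 1067, and 2713 were shared among lower genes against 945. Il6, Cd274, Rsad2 and Slamf7 were among the shared higher genes, Kif20a, Acat2, Trem1 and Cx3cr1 among the shared lower genes, and 0 genes passed in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.932. Part of this comes from the shared PBSDC libraries: with simulated groups that do not differ, r averaged 0.496 (0.434 to 0.565 in 40 simulations), and the covariance was 0.0181 against 0.678 observed. At most 0 genes were called in both comparisons in any such simulation by edgeR. The simulated spread came from the PBSDC and ZJDC libraries alone, without the division within OMVSSDC.

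Mitochondrially encoded genes took 7.32% ± 0.485 of counts in PBSDC, 5.20% ± 0.567 in ZJDC and 2.70% ± 1.51 in OMVSSDC (SD, n = 3). The OMVSSDC libraries held 1.81%, 1.86% and 4.44%. Each pair of groups gave p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 allows, and 0.21 after Benjamini-Hochberg adjustment. The share of the 10 most abundant genes was -2.29 percentage points in OMVSSDC relative to PBSDC, and 0.808 points once mitochondrially encoded genes were left out of the total.

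**Figure D4:**
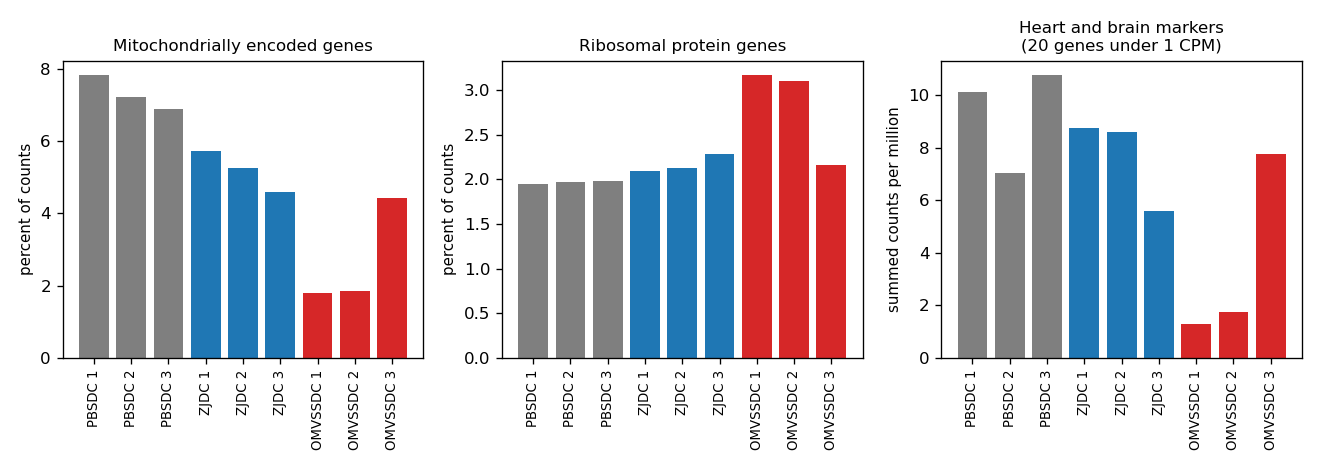
Share of counts from mitochondrially encoded genes and from ribosomal protein genes, and summed CPM of 20 heart and brain marker genes, in each of the 9 libraries. OMVSSDC replicates 1 and 2 lie apart from the other 7 in all 3 panels, at 1.81% and 1.86%, at 3.17% and 3.10%, and at 1.30 and 1.73 CPM.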

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

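The fits within the 7 libraries, without mitochondrially encoded genes, with the length and GC trend removed and without all OMVSSDC libraries, ZJDC against PBSDC without OMVSSDC replicate 3, and the Gene Ontology alternatives, were chosen only after the data were seen; the others were planned. OMVSSDC against PBSDC gave 5555 (glmTreat) to 8813 genes (without OMVSSDC replicate 3) and ZJDC against PBSDC 4350 (glmTreat) to 8242 (without OMVSSDC replicate 3). The balance of directions depended on scaling: 3866 higher and 3492 lower genes in OMVSSDC against PBSDC became 4672 and 2819 with library size alone and 3430 and 4153 with the length and GC trend removed, and 3193 and 3130 in ZJDC against PBSDC became 3631 and 2718, and 2891 and 3940. Scaling by library size alone moved the median log2 fold change of OMVSSDC against PBSDC from 0.0488 to 0.177. In OMVSSDC against ZJDC it turned the balance, from 99 higher and 127 lower genes to 115 and 91. OMVSSDC against ZJDC was not stable. Its 226 genes became 1580 with DESeq2, 617 with the length and GC trend removed, 355 within the 7 libraries, 2 with glmTreat, and 0 by edgeR with a replicate block (2955 at an unadjusted p under 0.05) or with only the 2 groups compared (2558); limma-voom gave 323. With 1 library left out it ranged from 0 to 6539, and the cause was not tested beyond the position of OMVSSDC replicate 3. With an estimated correlation 5, 3 and 2 lists passed in the 3 comparisons, where the preset gave 14, 13 and 8. With a replicate block 12, 13 and 8 passed, the p53 and NRF2 lists losing their call in OMVSSDC against PBSDC, and cameraPR gave 13, 14 and 8 and fry 21, 19 and 10. Both comparisons with OMVSSDC gave 12 and 9 lists within the 7 libraries, and 0 and 0 by camera with an estimated correlation (5 and 5 at an unadjusted p under 0.05). With 1 library left out the counts were 12 to 14, 12 to 13 and 7 to 8.

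Gene Ontology terms numbered 149 (12 higher and 137 lower) and 115 (28 higher and 87 lower) for both comparisons with PBSDC when all called genes were used, and 51 and 26 without OMVSSDC replicate 3, against 76 and 46. For OMVSSDC against ZJDC they numbered 0 by Fisher's exact test over 2-fold (94 at an unadjusted p under 0.05), 104 without OMVSSDC replicate 3 and 74 within the 7 libraries. The top 10 genes' share differed by 0.808, 0.782 and 0.0261 points once mitochondrial genes left the total, which turned its sign.

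Directions turned in genes that had not passed, and in Rps19. Cd80 in OMVSSDC against PBSDC was 0.0743 with library size alone and 0.19 within the 7 libraries, and -0.195 to 0.0516 with 1 library left out. Within the 7 libraries mt-Co1 was 0.35 and Rps19 -0.0398 against PBSDC, and B2m was 0.27 against ZJDC. Il6 against ZJDC was 0.00444 with the trend removed. The cause was not tested.

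Of named genes, 504 of 516 results with 1 library left out and 756 of 771 under planned settings of other kinds kept direction and side of the threshold in OMVSSDC against PBSDC. They were 504 of 511 and 646 of 651 in ZJDC against PBSDC, and 82 of 198 and 219 of 295 in OMVSSDC against ZJDC, where 110 and 72 lost a call. Apart from the panel, named genes were chosen from these data, many for large or clear changes. High shares of kept calls follow in part from that choice and do not measure stability over all genes. The labels do not say what replicate numbers mark. Deviations from group means of libraries with the same number correlated with r of -0.388 to 0.089 over the comparisons. This showed no pairing but cannot exclude one. The filter on low counts left out Cd83, Ccr7, H2-Ab1 and Ifnb1; without it Cd83 passed in OMVSSDC against PBSDC (adjusted p = 0.00421).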

Other observations

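The gene lists named here were planned, except the heart, brain and liver markers. The tests of explanations and the splits of the samples were chosen after the results they address were seen, except those of a wrong label on OMVSSDC replicate 3 by slopes and by counts of called genes, and of length and GC bias in mitochondrial genes.

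Genes of myeloid identity moved both ways in both treated groups. Of 25 measured, 12 rose and 7 fell in OMVSSDC against PBSDC and 11 rose and 7 fell in ZJDC against PBSDC, and the list did not pass (adjusted p = 0.894 and 0.862). Clec10a, a lectin of conventional dendritic cells, rose by 1.69 and 1.24 on the log2 scale, Itgax, which encodes CD11c, by 0.98 and 1.06, and Adgre1, which encodes F4/80, by 1.01 and 0.74. Csf1r, the receptor of macrophage growth factor, fell from 1131 CPM in PBSDC to 564 CPM in OMVSSDC and 554 CPM in ZJDC. Lyz2, lysozyme, fell by 1.48 and 1.63, and Mertk, an efferocytosis receptor, by 1.48 and 1.41. Itgam, which encodes CD11b, fell from 336 CPM to 119 and 164 CPM. Of 9 MHC class II genes 4 rose in each comparison, among them Cd74, the invariant chain gene, by 0.85 and 0.84, and that list did not pass (0.414 and 0.517).

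Sensors of nucleic acids and bacterial products also divided, with 12 higher and 11 lower of 34 in OMVSSDC and 14 and 8 in ZJDC (list adjusted p = 0.655 and 0.423). Nod1, a sensor of bacterial peptidoglycan, rose by 1.91 and 1.38 and Casp4, which binds lipopolysaccharide, by 1.38 and 1.40, while the endosomal RNA receptor genes Tlr8 and Tlr13 fell by 1.15 and 1.18 in OMVSSDC and by 1.21 and 0.97 in ZJDC. Among genes of migration and metabolism, Cxcr4, a chemokine receptor, rose by 1.93 and 1.72, Sema7a by 2.96 and 2.28, and Trib3, a stress response gene, by 2.49 and 1.82; Actb fell by 1.10 and 0.97 and Ldha, lactate dehydrogenase, by 1.02 and 1.06. The cytoskeleton, glycolysis and integrated stress lists did not pass in OMVSSDC against PBSDC (adjusted p = 0.917, 0.438 and 0.380) or in ZJDC against PBSDC (0.771, 0.555 and 0.717).

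Markers of other cell types stayed low. Summed epithelial markers were 47.0 to 50.5 CPM in PBSDC, 98.3 to 109 in OMVSSDC and 100.2 to 108 in ZJDC; nearly all of this was 1 gene, St14, with 606 to 797 counts in PBSDC and 1259 to 1944 in the treated groups, while Epcam, Krt8, Krt18, Krt19 and Cdh1 had 0 to 4. Of the epithelial list, 2 of 3 measured genes were higher in OMVSSDC and 1 in ZJDC (list adjusted p = 0.326 and 0.244). Lymphocyte markers were 13.1 to 15.8 CPM in PBSDC and 19.1 to 24.7 in the treated groups (0.710 and 0.555), with Lck at 73 to 117 and 150 to 291 counts. Fibroblast and endothelial markers were 19.3 and 19.8 CPM in OMVSSDC replicates 1 and 2, 40.5 in replicate 3, 31.7 to 37.2 in PBSDC and 22.9 to 31.8 in ZJDC (0.928 and 0.761); in OMVSSDC against ZJDC within the 7 libraries that list was higher (adjusted p = 0.0159, and adjusted p = 0.254 with an estimated correlation). Granulocyte and erythroid markers, of which 0 could be tested, were 13.3 CPM in OMVSSDC replicate 1 and 1.06 to 2.64 elsewhere. Liver markers were detected with 11 of 11 genes in OMVSSDC replicate 2 and 2 to 4 in each other library; their sums lay nearer, at 2.92 CPM there and 0.690 to 2.23 CPM in the others.

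OMVSSDC replicate 3 stood apart from replicates 1 and 2. A swap with a ZJDC library stays open. ZJDC replicate 3 lay at a chi-square per degree of freedom of 54.7 and 58.2 from OMVSSDC replicates 1 and 2. OMVSSDC replicate 3 lay farther from them, at 62.4 and 65.1. ZJDC libraries lay at most 9.01 from one another, which argues against a swap only if OMVSSDC replicates 1 and 2 are no batch. A batch of replicates 1 and 2 is a candidate explanation: their heart and brain traces reached at most 1.73 CPM, and the other 7 had at least 5.60 CPM, but that batch holds OMVSSDC libraries only, so batch and group cannot be told apart in it. A ZJDC library under a wrong label also stays open, since the tests were mixed: the slopes of replicate 3 towards replicates 1 and 2 (0.0692 to 0.147) lay within the ZJDC range, up to 0.260, but of its counts of genes called alone against ZJDC pairs, 144, 540 and 554, the lowest alone lay within the ZJDC range, up to 208. Among genes over 1.5-fold apart between replicates 1 and 2 and a ZJDC pair, replicate 3 lay at least 0.75 of the way to replicates 1 and 2 in 3.83% to 4.29%, and the third ZJDC library in 0.855% to 2.91%. As a share of that way, the median position of replicate 3 was -0.00372 to 0.0913, and that of the third ZJDC library -0.127 to 0.227. Some genes follow the label: Rsad2 stood at 326 CPM in replicate 3, 327 and 334 CPM in replicates 1 and 2 and 204 to 216 CPM in ZJDC, Sh2d6 at 351, at 333 and 332 and at 230 to 237 CPM, and Heatr9 at 28.2, at 27.2 and 29.1 and at 13.5 to 17.4 CPM. Other genes stood nearer to ZJDC. Ccl5 stood at 146 CPM in replicate 3, 352 and 345 CPM in replicates 1 and 2 and 107 to 132 CPM in ZJDC. Cd40 stood at 57.5, at 80.7 and 78.5 and at 47.0 to 51.8 CPM. These examples of both kinds were picked after their values were seen. A biological difference between cultures was not tested.

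Most mitochondrially encoded genes were lower in both treated groups, 11 of 12 measured in OMVSSDC and 9 in ZJDC. A lower recovery of all these transcripts alike is argued against, since their log2 fold changes in OMVSSDC spanned 3.77, beyond the 1.46 that 4 times their median standard error allows, and in ZJDC spanned 3.08. Bias from gene length or GC content, as far as other genes share it, was too small for these falls in OMVSSDC. Over the bulk of genes the fitted trend spanned at most 0.512 on the log2 scale in a library. The 11 lower genes stood at -4.12 to -1.60. That 100% of them kept their call with the trend removed follows from its size and adds nothing. A bias particular to these genes was not tested. That count was not made for ZJDC. In a fit without the OMVSSDC libraries, 11 of 12 genes were lower in ZJDC than in PBSDC and mt-Co1 was higher. A handling difference between the ZJDC and PBSDC libraries was not tested. The batch of OMVSSDC replicates 1 and 2 could not set that difference by design, since it holds no ZJDC or PBSDC library. It cannot be told apart from the group in the share of these 2 libraries, at most 1.86% of counts against 4.44% in replicate 3, although 11 of 12 genes were also lower in replicate 3 within the 7 libraries. A treatment effect stays open.

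Of 53 ribosomal protein genes 32 were higher in OMVSSDC, and the list passed (adjusted p = 0.00691, and adjusted p = 0.732 with an estimated correlation). Length or GC bias as the whole cause is argued against, since 28 of the 32 genes kept their call with the trend removed. It may be part of the cause, since the median log2 fold change of the list moved from 0.429 to 0.336. The trend was also largest in the possible batch. It spanned 0.512 and 0.436 on the log2 scale in OMVSSDC replicates 1 and 2 and 0.0982 to 0.234 in the other 7 libraries. With that trend removed and the preset correlation, the list still passed camera (adjusted p = 0.0242). The batch of replicates 1 and 2 may account for it, since replicate 3 held 2.16% of counts in these genes, within the 2.29% reached by ZJDC. An effect of the treatment on replicates 1 and 2 alone stays open.

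The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. For OMVSSDC against PBSDC 1 of 10 splits, the real one, gave as many genes (7358, highest other 0), and for ZJDC against PBSDC also 1 (6323, highest other 0). Splits that mix these groups put the large difference between them into the spread. The 0 genes of the other splits therefore say nothing about chance. For OMVSSDC against ZJDC 2 of 10 gave as many as the real 226. The other, with 2991 genes, set OMVSSDC replicates 1 and 2 and ZJDC replicate 3 against the rest, which points to a structure of the samples. A swap of ZJDC replicate 3 with OMVSSDC replicate 3 would make the same division.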
